A study of Pseudomonas putida KT2440 with 2 samples.

How the data were processed

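RNA-seq files of 2 libraries of Pseudomonas putida KT2440 were analysed, 1 from a culture at 30 °C and 1 from the same culture system 2 h after it had reached 10 °C. Total RNA was reverse transcribed with random hexamers, per the labels' protocols. The labels mention 3 parallel RNA samples per time point, but 1 library per temperature was given and nothing states whether RNA was pooled. Grouping followed the labels. The reads were aligned with Bowtie, per the submitters' processing notes, and its version, mismatch and multiple-mapping settings were not given in the sources used here. The deposited alignments name 1 chromosome sequence of KT2440, and all coordinates are on that sequence, counted from 1. Each alignment holds a read of 32 bases.

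The deposited tables give a read count per ORF, rRNA, tRNA or intergenic region, per the file headers, without normalization. Per the file headers, the authors also listed RPKM (reads scaled to feature length and to a total of reads), which served here only to check the total they divided by. Back-calculation gave totals of 279080 and 339778, close to the numbers of alignments. The deposited columns of bases covered and of the fraction of each feature covered (coverage) showed that each ORF with no base covered was listed with 1 read, and this was so for 1239 ORFs at 30 °C and 747 at 10 °C. Such counts were set to 0. At 30 °C 4 of these ORFs held the midpoint of an aligned read all the same, 1 of them among the ORFs called higher, and at 10 °C 0 did. A recount of alignments that overlap each ORF on either strand equalled the listed count exactly for 93.3% of ORFs at 30 °C and 93.1% at 10 °C, so the tables do not use strand. Reads of an ORF and of an antisense or overlapping transcript cannot be told apart, and a read that overlaps 2 features is counted in each. Regions listed as upstream of an ORF lay on its low-coordinate side in all 4508 cases, whatever its strand, and are named here by both neighbours or by coordinates.

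The ORF table held 5420 ORFs, 21 rRNA genes and 74 tRNA genes. Comparisons of ORFs were scaled to the total of ORF reads, and those of intergenic regions to the total of intergenic reads, or to that of ORF reads where stated. Depth was 236857 ORF reads at 30 °C and 248532 at 10 °C, with 963 and 1264 ORFs at 20 reads or more. The 10 ORFs with most reads took 19.3% and 20.9% of the ORF reads. Distinct combinations of start and strand made up 50.9% of alignments at 30 °C and 43.9% at 10 °C.

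No test across samples was possible with 1 library per group. For each feature the ratio of CPM (counts scaled to that total; 10 °C over 30 °C) was given with an exact conditional Clopper-Pearson 95% interval of the ratio of 2 Poisson counts. A feature with a combined count of at least 20 was called higher or lower when its ratio was at least 2 or at most 0.5 and the interval excluded 1. Where 1 library had 0 reads, the bound was taken against a floor of 3 reads per library. Log2 ratios used 0.5 added to each count. Shares carry exact Clopper-Pearson 95% intervals. Each gene list was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size drawn from 20 expression bins. Lists with fewer than 3 countable members received no percentile.

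The rule for named ORFs was set before the data were examined. It took the 15 highest-ranked ORFs in each direction, ranked by the interval bound nearest 1, the countable cold shock domain genes, the 5 ORFs with most reads per library, and in each list up to 2 higher and 2 lower members. It also took the 5 highest-ranked intergenic regions in each direction. Further list members are printed with their reads to describe the lists and were chosen after their values were seen. The rule took 86 ORFs, 72 of them with a symbol. Of those without a symbol only the 2 first-ranked in each direction, PP_1689 and PP_0168 are printed. The lists were patterns of symbols and product names, but the files give no product names, so only symbols acted. After the data were seen, cspA-1 and cspA-2 were added to the cold shock list, and metG, cysB and cysA, which are not biosynthetic genes, were removed from amino acid biosynthesis. A reference gene table of another assembly (5723 genes) shared 0 locus tags and 740 symbols with the files, and no coordinate of it is used.

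Scaling alternatives used TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 in R 4.3.3, neither of which was used for a test. Other alternatives were all aligned reads as the total, no minimum count or 100, a 3-fold rule, reads recounted from the alignments by midpoint, alignments of the same start and strand counted once, the deeper library thinned to the depth of the other, the 10 most abundant features left out, and 181 ORFs that share the stem of their symbol with another ORF left out. The remaining analysis used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. GC content was taken from the aligned reads within each ORF, each start and strand once, as no genome was used.

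The rule of size was tested on simulated counts for the 5420 ORFs at the depths of these libraries, with 50 ORFs changed per fold. It called 96% of ORFs made 4-fold higher, 100% of those made 8-fold higher, 74% of those made 4-fold lower and 60% of those made 8-fold lower. The missed lower ones had fallen under 20 reads. Of 1653 countable ORFs simulated without change, 62 (3.75%) were called, and 96.4% of intervals held the true ratio. The simulated counts were Poisson draws, without repeated fragments or variation between cultures. These rates are therefore not the error rates of the calls in the real libraries.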

Results

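Transcripts of Pseudomonas putida KT2440, a soil bacterium, were sequenced before and after a drop in growth temperature. The culture grew in a fermenter on mineral medium with 15 mM succinate as the carbon source. 1 library came from cells in mid-exponential phase at 30 °C, and 1 came from cells taken 2 h after the culture had been brought to 10 °C. The 30 °C library held 276863 alignments of 32 bases and the 10 °C library held 339551. The deposited gene tables listed 5420 open reading frames (ORFs), of which 1396 carried a gene symbol. Reads in ORFs numbered 236857 at 30 °C and 248532 at 10 °C, with a median of 3 and 5 reads per ORF. The tables listed no covered base for 1239 ORFs at 30 °C and 747 at 10 °C, which were counted as 0, and a count of 0 allowed up to 12.7 and 12.1 CPM (reads of a feature scaled to a common total of ORF reads). With 1 library per temperature there was no replicate check, so each comparison is between these libraries and not between the temperatures. The reads were amplified and carried no molecular identifiers, so intervals and floors cover counting error only.

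The first question was which genes differed in read count after the shift to 10 °C. Of 9 countable genes listed for the breakdown of branched-chain and aromatic amino acids, 1 of which (putA) acts on proline instead, 6 were higher in the 10 °C library. The higher ones included hpd (4-hydroxyphenylpyruvate dioxygenase, in tyrosine breakdown), bkdA1 and bkdA2 (subunits of the branched-chain keto acid dehydrogenase). The heat shock chaperone genes groEL, groES, dnaK and htpG were lower, as were genes for succinyl-CoA synthetase (sucC, sucD), the glyoxylate shunt enzyme aceA and 7 of 9 genes of the ATP synthase. Of 76 genes of amino acid synthesis 40 were lower, with ilvC (branched-chain amino acids) and glnA (glutamine synthetase) in front. The highest ratios of all belonged to PP_1691 and PP_1690, neighbouring ORFs without a symbol, which had 1 read each at 30 °C and 1500 and 592 reads at 10 °C.

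Of the 5420 ORFs, 1853 (34.2%) had at least 20 reads in the libraries together, and 607 of these were higher in the 10 °C library, 337 were lower and 909 were neither. An ORF counted as higher or lower when its ratio of CPM was at least 2 or at most 0.5 and the whole 95% counting interval lay on the same side of 1. At least 10-fold differences occurred in 134 higher and 43 lower ORFs. A symbol was present for 24.5% of the higher ORFs and 69.7% of the lower ones, against 45.4% of all ORFs with at least 20 reads. 23 of the higher ORFs had a count of 0 at 30 °C, whereas 1 of the lower ORFs, trpB, had a count of 0 at 10 °C. The split of 64.3% higher calls depended on scaling, because the median log2 ratio of the counted ORFs was 0.35 with plain totals. TMM factors lowered every log2 ratio by a common amount (-0.41) and DESeq2 size factors did so by a similar amount (-0.44). With these the median moved to -0.06 and -0.09, and the calls to 467 higher and 483 lower (TMM) or 464 higher and 485 lower (DESeq2). All 337 lower ORFs stayed lower under both, as they had to, because both settings lowered every ratio.

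**Figure D1:**
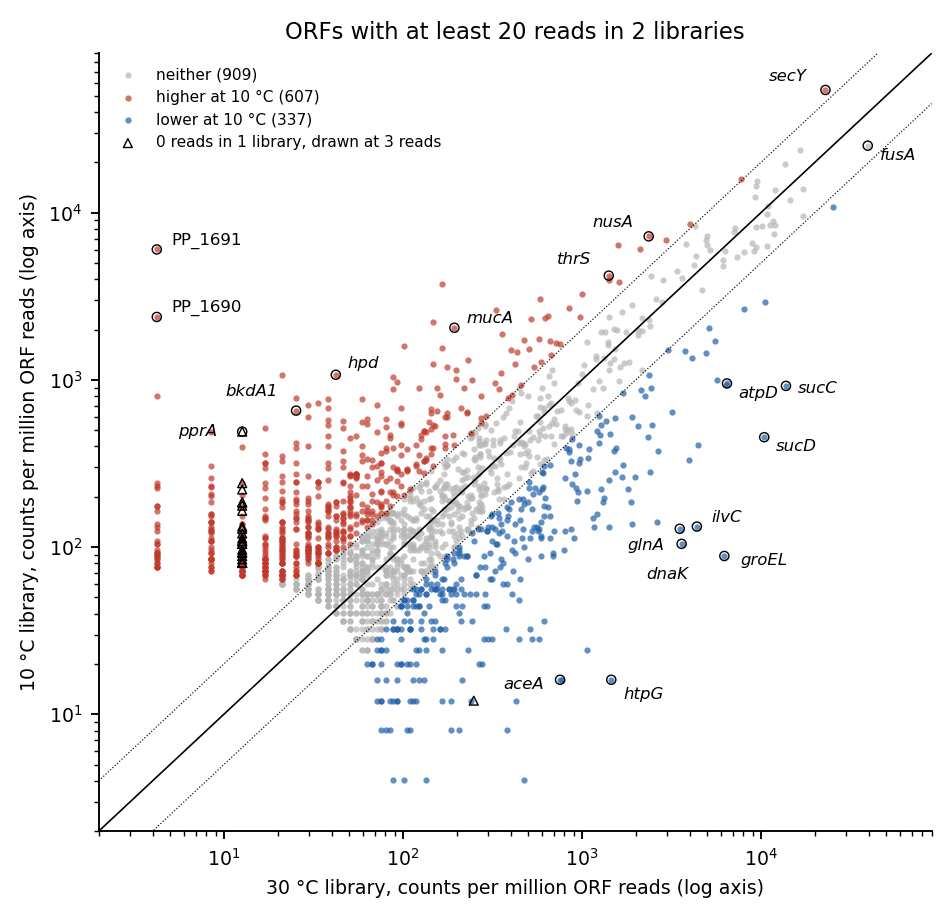
CPM, scaled to ORF reads, in the 30 °C library (x axis, log) and the 10 °C library (y axis, log) for the ORFs with at least 20 reads, with 607 higher ORFs in red, 337 lower in blue and 909 in grey; the solid line marks equality, the dotted lines mark 2-fold and triangles mark ORFs with a count of 0 in 1 library, drawn at 3 reads. PP_1691, with 1 read at 30 °C and 1500 at 10 °C, lies at the upper left, and groEL, with 1482 and 22 reads, at the lower right.

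PP_1691 had a ratio of 1430 (95% counting interval 256 to 56501) and PP_1690 a ratio of 564 (101 to 22322). PP_1690 lies at 1882708 to 1883189 and PP_1691 at 1883440 to 1883663 on the chromosome sequence used by the authors. Counting alignments with the same start and strand once lowered these ratios to 273 and 278. pprA had 0 reads at 30 °C and 122 at 10 °C, at least 38.8-fold higher against the floor of 3 reads (lower bound of the exact interval 31.0). hpd had 10 and 267 reads (ratio 25.4, 13.6 to 53.7), bkdA1 had 6 and 163 (25.9, 11.6 to 71.6), and bkdA2 had 0 and 60, at least 19.1-fold higher against that floor (exact lower bound 15.0). The other 11 of the 15 highest-ranked ORFs, PP_1691 and PP_1690 among them, carried no symbol. PP_1689, which lies beside PP_1690 in the same stretch of raised reads, was also among them (39 and 937 reads, ratio 22.9, 16.6 to 32.4).

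**Figure D2:**
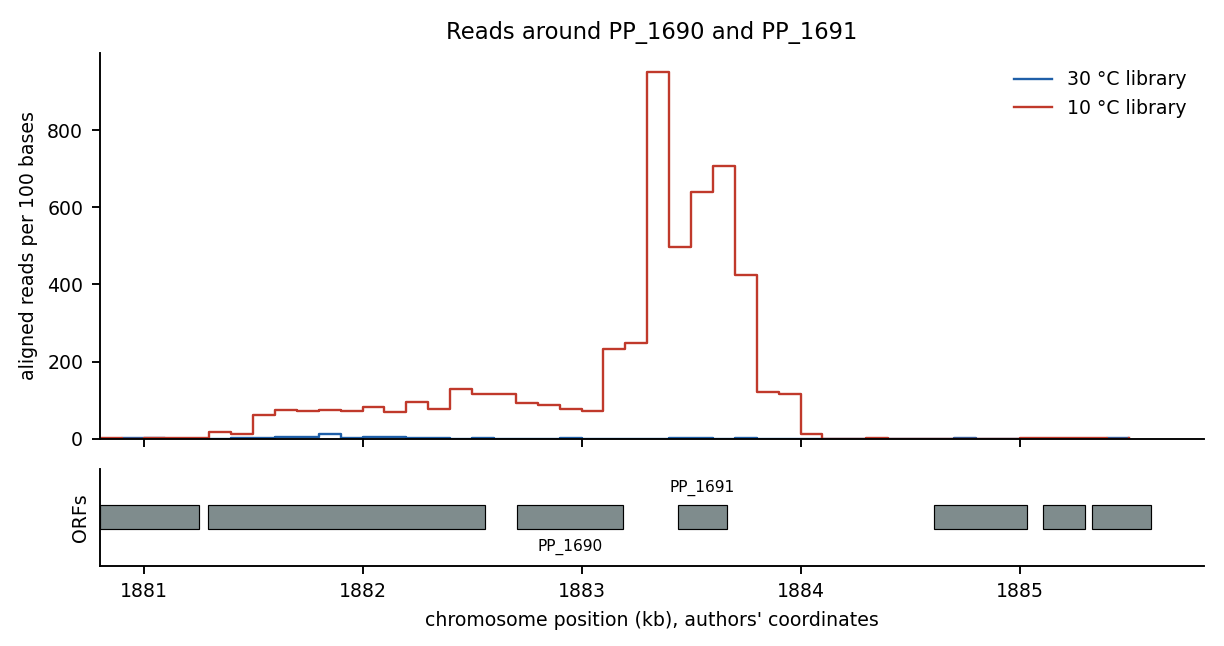
Aligned reads per 100 bases of the chromosome (y axis) along the stretch that holds PP_1690 and PP_1691 (x axis, kilobases), for the 30 °C library in blue and the 10 °C library in red, with ORFs drawn as boxes below. The 10 °C reads rose within PP_1689, with 39 reads at 30 °C and 937 at 10 °C, and ran on through PP_1690. They continued through the region at 1883190 to 1883439, which had 1 read at 30 °C and 1693 at 10 °C, and past PP_1691.

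Among the 15 highest-ranked lower ORFs, 13 carried a symbol. groEL had 1482 reads at 30 °C and 22 at 10 °C and was 70.7-fold lower (46.5 to 113), and htpG had 346 and 4 and was 90.8-fold lower (35.1 to 335). groES was 44.1-fold lower, dnaK 34.5-fold (23.4 to 53.1), ilvC 33.1-fold (23.4 to 48.3) and glnA 27.4-fold (19.2 to 40.3). sucD was 23.0-fold lower, kgdB (2-oxoglutarate dehydrogenase) 18.7-fold and sucC 15.0-fold. aceA was 47.0-fold lower (18.0 to 174), gcvP-1 of the glycine cleavage system 48.0-fold (18.4 to 178) and leuD of leucine synthesis 35.7-fold (11.9 to 176). trpB, a tryptophan synthase subunit, had 59 and 0 reads, at least 20.6-fold lower against the floor (exact lower bound 16.3). The ORFs without a symbol were PP_5232, with 113 and 1 reads, and PP_0861, with 90 and 2. Counting each start and strand once left groEL 44.2-fold, groES 20.0-fold, ilvC 22.6-fold, glnA 19.5-fold, kgdB 12.9-fold, sucD 9.93-fold and sucC 7.16-fold lower.

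The most abundant ORFs belonged largely to translation and secretion. The gene with most reads at 30 °C was fusA (elongation factor G, PP_0451), with 9378 reads at 30 °C and 6264 at 10 °C. It was 1.57-fold lower and passed no threshold, and the same held for tuf (elongation factor Tu, PP_0452), with 4058 and 2371 reads. Under TMM both were lower, 2.09-fold and 2.39-fold, and both share their symbol with another ORF. Whether these ORFs share reads was not tested, so their counts are uncertain. secY, the channel subunit of the secretion translocase, had 5441 and 13494 reads and was 2.36-fold higher (2.29 to 2.44). That call ended under TMM (1.78), DESeq2 (1.74) and when each start and strand was counted once (1.25). rpsA was 2.34-fold lower (2.23 to 2.45), a call that ended when each start was counted once (1.55). rpsM had a ratio of 2.05, which ended under TMM (1.54), while rpsC and rplF had ratios of 0.808 and 1.44. PP_0168, an ORF of 26048 bases, had 3915 and 5919 reads and a ratio of 1.44.

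Gene lists were compared by the median log2 ratio of their members with at least 20 reads and by its percentile among 10000 random lists matched on expression. The random lists were drawn from all countable ORFs, while each list member carries a symbol. ORFs with a symbol had 149 higher and 235 lower calls, against 607 and 337 among all ORFs. The percentiles therefore lean low, by an amount that was not measured. The gene lists were fixed beforehand except for 5 symbols changed after the data were seen. cspA-1 and cspA-2 were added to the cold shock list, and metG, cysB and cysA were removed from amino acid biosynthesis. The list of cold shock domain proteins so completed had 1 countable member of 3. It was cspA-2, with 19 reads at 30 °C and 15 at 10 °C, a ratio of 0.752 (0.356 to 1.56), so no difference was detectable at this depth. cspA-1 had 2 and 6 reads and cspD had 2 and 4. The helicases, exonucleases and ribosome assembly factors linked to the cold response had 19 countable members, of which 3 were higher, 2 were lower and 14 were neither (median 0.29, percentile 67.5). The sign of that median turned under TMM (-0.12) and DESeq2 (-0.15). rbfA, a ribosome maturation factor, was 4.40-fold higher (3.02 to 6.58) and the elongation factor gene nusA 3.06-fold (2.78 to 3.37), or 2.21-fold for nusA with each start and strand counted once. tig (trigger factor) was 3.96-fold lower (3.16 to 5.00) and pnp (polynucleotide phosphorylase) 2.70-fold (2.31 to 3.17). infB, which encodes initiation factor IF-2, was the remaining higher member, at 2.87-fold. The DEAD-box helicase gene csdA had 7 and 15 reads and the ribonuclease gene rne had 485 and 459.

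Of 51 ribosomal protein genes, 3 were higher, 2 were lower and 46 were neither (median -0.19, percentile 24.7). Under TMM 1 was higher and 7 were lower. The higher members were rpmF (3.63-fold, 2.95 to 4.51), rpmJ (2.32-fold) and rpsM, and the last 2 calls ended under TMM. With each start and strand counted once rpmF was 2.14-fold higher and the ratios of rpmJ and rpsM fell to 1.29 and 1.24, which ended both calls. rpsB was 2.51-fold lower, a call that ended when each start and strand was counted once (1.91). Translation factors and aminoacyl-tRNA synthetases had 2 higher, 13 lower and 15 other members of 30 (median -0.81, percentile 1.02), and 22 were lower under TMM. thrS (threonyl-tRNA synthetase) was 2.98-fold higher (2.63 to 3.38) and prfC 2.02-fold, a call that TMM ended (1.52). tsf (elongation factor Ts) was 5.43-fold lower (4.19 to 7.11) and valS 4.05-fold (3.22 to 5.14).

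Heat shock chaperones and proteases had no higher, 11 lower and 9 other members of 20 (median -1.20, percentile 0.26). Besides groEL and htpG these included grpE, with 145 reads at 30 °C and 9 at 10 °C, and dnaJ, with 84 and 21. Outer membrane porins and efflux genes had no higher and 7 lower members of 13 (median -1.01, percentile 2.02). The efflux pump genes mexC and mexD were 23.1-fold (6.02 to 197) and 18.7-fold lower (8.83 to 47.6), and oprD had 334 and 63 reads. RNA chaperones, small RNA regulators and RNA turnover genes had 1 higher, 1 lower and 8 other members (median -0.14, mean 0.03, percentile 28.4). hfq, the RNA chaperone gene, was 4.09-fold higher (3.01 to 5.64; 2.90 with each start and strand counted once), and eno, which encodes the glycolytic enzyme enolase, 4.45-fold lower (3.29 to 6.13). crc, a regulator of carbon catabolite repression, had 49 and 44 reads.

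The list of succinate uptake and the tricarboxylic acid cycle had 1 higher, 19 lower and 2 other members of 22, and its median of -1.74 lay below those of all 10000 random lists. The members together had 15523 reads at 30 °C and 3053 at 10 °C. The succinate transporter gene dctA had 340 and 118 reads, acnB (aconitase) 631 and 94, and gltA (citrate synthase) 452 and 150. mqo-2, a malate:quinone oxidoreductase gene, was 7.26-fold higher (4.92 to 11.1). The respiratory chain and ATP synthase had 1 higher, 21 lower and 9 other members of 31 (median -1.61, also below all random lists). Most of the lower members lay in the atp and nuo operons, and the sdh-suc cluster gave several members of the tricarboxylic acid cycle list. Genes of an operon can share a transcript, which the random lists took no account of. These counts and percentiles may therefore rest on few transcripts. atpD was 6.79-fold lower (5.92 to 7.82) and atpG 5.69-fold (4.97 to 6.53), or 5.16-fold and 3.67-fold with each start and strand counted once. petB was the higher member (2.20-fold, 1.11 to 4.59), a call that ended under TMM (1.65) and when reads were recounted from the alignments (1.99). The cytochrome bo oxidase genes cyoA, cyoB, cyoC and cyoD were neither higher nor lower, with 1031 and 1378 reads for cyoB.

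Ratios differed along the atp and sdh-suc gene clusters, which were chosen for display after the values were seen. In the atp operon the ratio of 10 °C to 30 °C was 1.09 (0.857 to 1.39) for atpI, the first gene, 0.278 (0.255 to 0.302) for atpA and 0.147 (0.128 to 0.169) for atpD. From sdhC to sucD it went from 0.518 (0.424 to 0.631) to 0.0435 (0.0357 to 0.0526). nusA, infB and rbfA were higher while pnp, at the far end of the same cluster, was lower. In the ribosomal protein cluster the ratio was 0.626 for rplX and 1.96 for rplO, just before secY.

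**Figure D3:**
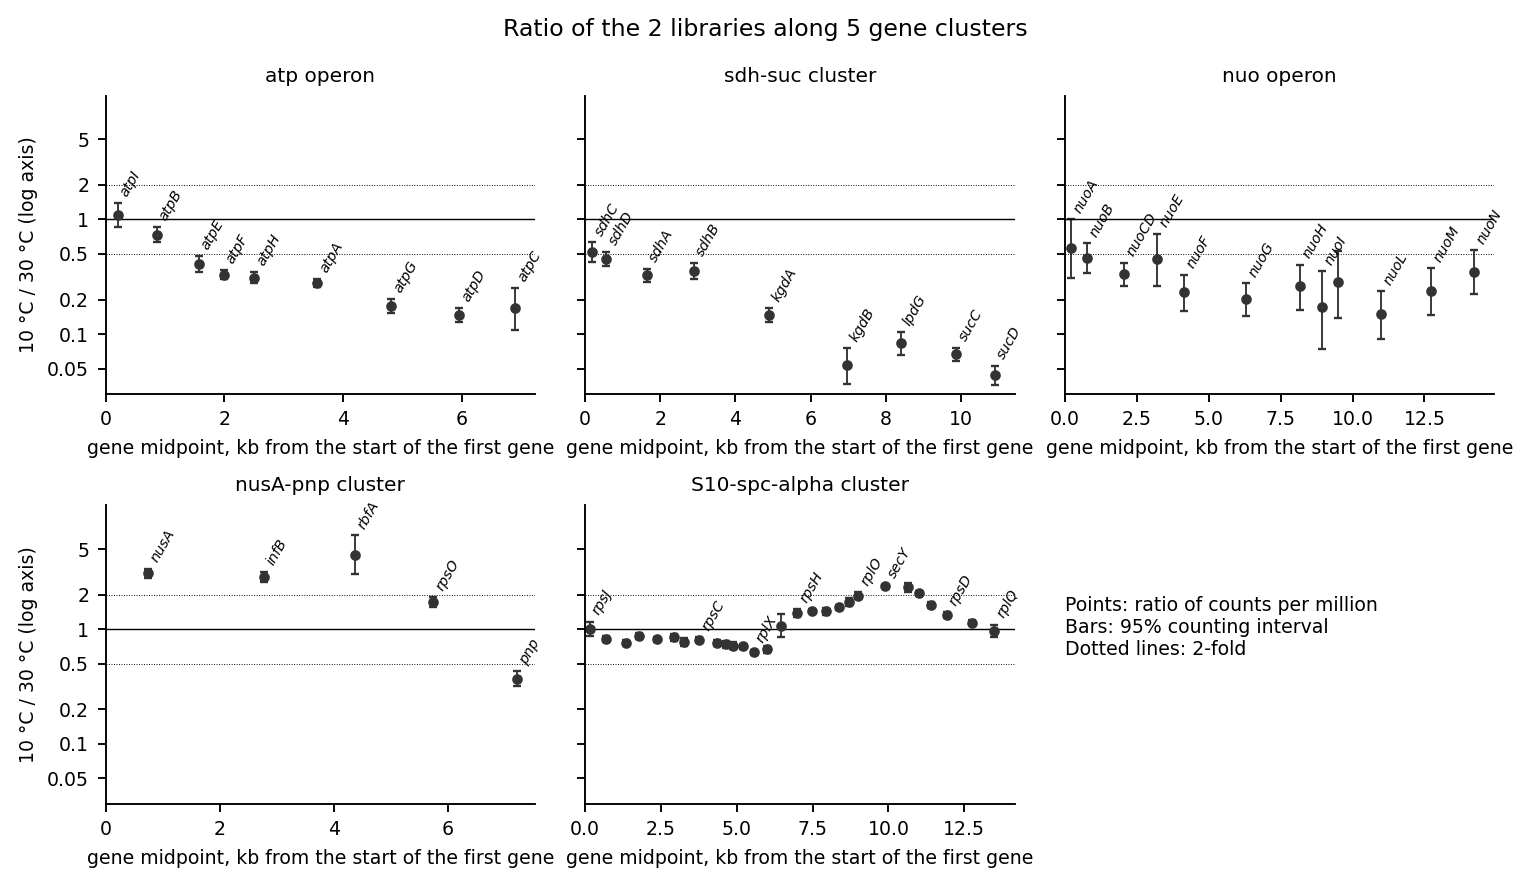
Ratio of CPM of the 10 °C to the 30 °C library (y axis, log) by gene midpoint in kilobases from the start of the first gene (x axis) in 5 gene clusters, with bars for the 95% counting interval and dotted lines at 2-fold. In the atp operon the points go from 1.09 for atpI to 0.147 for atpD, and in the ribosomal protein cluster secY stands at 2.36.

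Amino acid biosynthesis had 3 higher, 40 lower and 33 other members of 76, with a median of -1.08 below all random lists. Besides ilvC and glnA, argG had 467 reads at 30 °C and 65 at 10 °C, ilvB 1055 and 102, and cysNC 277 and 33. The higher members were aroE at PP_3768 (1 and 27 reads, ratio 25.7, 4.24 to 1054), aroE at PP_0074 (5.72, 1.67 to 30.3) and the shikimate kinase gene aroK (8 and 25 reads). The aroK call ended under TMM (2.24, interval across 1). The aroE ORFs share a symbol, so their counts are uncertain, and with each start and strand counted once both fell under 20 reads, though their ratios stayed at 17.0 and 4.67. Nitrogen assimilation had no higher, 4 lower and 2 other members of 6 (median -2.35, percentile 0.14), with glnA and gltB (glutamate synthase, 5.15-fold lower) in front. Without a minimum count the median over 16 members was -1.10. Of 9 genes of branched-chain and aromatic amino acid catabolism, 6 were higher, 1 was lower and 2 were neither, and the median of 3.63 lay above all random lists. Without a minimum count the median over all 20 members was 0.91, and the minimum can favour genes with few reads at 30 °C that are high at 10 °C. Under TMM 5 were higher, as the phhR call ended (1.79). bkdB had 2 and 52 reads, lpdV had 2 and 32 and phhR, the regulator of phenylalanine breakdown, had 8 and 20. bkdA1 and bkdA2 are neighbours on the chromosome, and bkdB and lpdV belong to the same dehydrogenase. All of these bkd and lpdV genes may share a transcript, so the members are not independent. The lower member was putA, 2.67-fold lower (1.29 to 5.95), a gene of proline breakdown that the list's name does not cover.

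**Figure D4:**
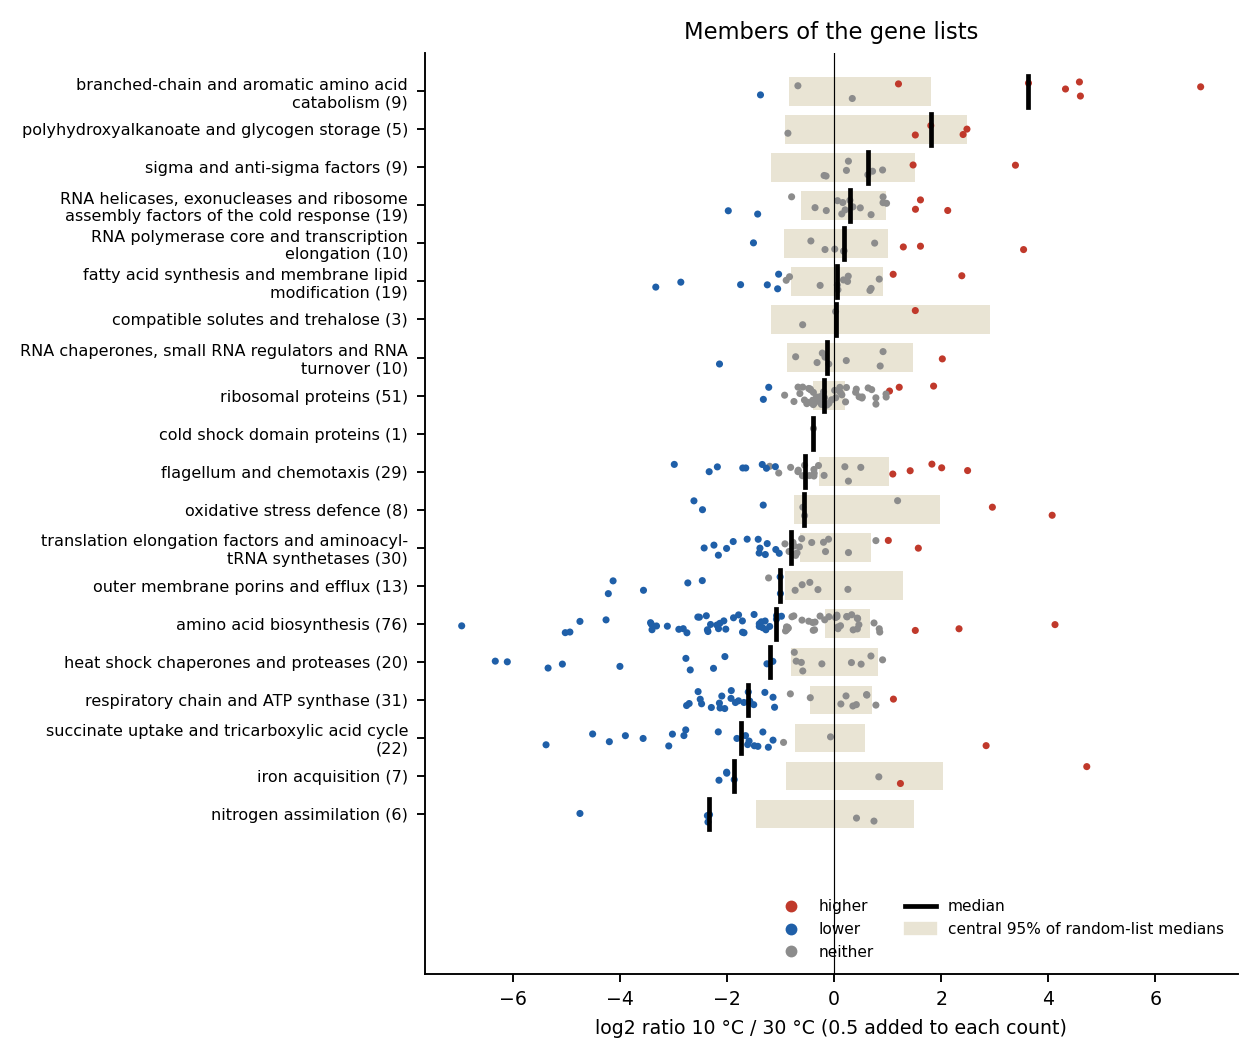
Log2 ratio of 10 °C to 30 °C (x axis, 0.5 added to each count) of each countable member of the gene lists (y axis, members in parentheses), with black bars for the medians and shaded bands for the central 95% of medians of random lists. The catabolic list has a median of 3.63 and the tricarboxylic acid cycle list a median of -1.74, both outside their bands.

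Fatty acid and membrane lipid genes had 2 higher, 6 lower and 11 other members of 19 (median 0.06, mean -0.36, percentile 53.0), and the median turned negative under TMM (-0.35). plsX was 5.25-fold higher (4.16 to 6.69) and fabD 2.16-fold, a call that TMM ended (1.62). The acetyl-CoA carboxylase genes accC-1 and accB were 10.2-fold (7.52 to 14.1) and 7.44-fold lower (4.79 to 12.1). Flagellum and chemotaxis genes had 5 higher, 8 lower and 16 other members of 29 (median -0.55, percentile 0.17), and 13 were lower under TMM. The summed reads went the other way (ratio 2.07), because the abundant members fliC, with 947 and 2123 reads, fliD (4.03-fold higher, 3.60 to 4.52, or 2.97-fold with each start and strand counted once) and fliS (5.69-fold, 4.01 to 8.30) were higher. The fliC call ended under TMM (1.61). With a minimum of 100 reads, 4 members remained and the median turned to 1.55. fliF, a basal body gene, was 9.09-fold lower (2.79 to 46.9) and cheY 4.80-fold (2.08 to 12.9).

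Sigma and anti-sigma factors had 2 higher and 7 other members of 9 (median 0.63, percentile 81.2). The list's pattern missed the sigma factor gene algT, which had 35 and 551 reads and was 15.0-fold higher. mucA, the anti-sigma factor gene of AlgT, was 10.6-fold higher (7.81 to 14.6), or 6.77-fold with each start and strand counted once, and rpoS, the stationary phase sigma factor gene, 2.82-fold (1.73 to 4.74). The heat shock sigma factor gene rpoH had 40 and 79 reads. RNA polymerase and transcription elongation genes had 3 higher, 1 lower and 6 other members of 10 (median 0.18, percentile 60.2), with a negative median under TMM (-0.23). greB had 2 and 30 reads (ratio 14.3, lower bound 3.63), rho had 231 and 594, a call that ended under TMM (1.84), and greA was 2.88-fold lower (1.89 to 4.49).

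Oxidative stress genes split into 2 higher, 3 lower and 3 other members of 8 (median -0.57, mean 0.08, percentile 4.76). The catalase genes katA (18.8-fold, 7.07 to 70.8) and katE (8.89-fold, 2.75 to 45.7) were higher, while gshA of glutathione synthesis was 6.39-fold lower and the superoxide dismutase gene sodB 5.58-fold. Iron acquisition genes had 2 higher, 4 lower and 1 other member of 7 (median -1.87, mean -0.18, percentile 0.14). The interval of that median ran from -2.15 to 4.72. fepA, a ferric siderophore receptor gene, had 1 and 41 reads (ratio 39.1, 6.63 to 1581) and pfrA had a ratio of 2.44, which TMM ended (1.83). exbB and exbD, which energise outer membrane uptake, were 4.07-fold and 4.55-fold lower. Storage genes of polyhydroxyalkanoate and glycogen had 4 higher and 1 other member of 5 (median 1.81, percentile 89.4), but 3 higher and 1 lower under TMM, and a median of 0.20 over 10 members without a minimum count. glgB (ratio 6.04, 1.78 to 31.8) and glgP (6.35, 1.88 to 33.4) rested on 3 reads each at 30 °C, and with each start and strand counted once both fell under 20 reads, though their ratios stayed at 5.01 and 5.34. The list of compatible solutes and trehalose had 1 higher member of 3 (median 0.03, percentile 29.2). It was glgA, a glycogen synthase gene and so not itself a compatible solute gene, with 7 and 22 reads. That call ended under TMM (ratio 2.25, interval across 1), and betB had 29 and 31 reads. The list of transposons and prophages had no member with at least 20 reads.

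The second question was how reads outside ORFs differed. The region with the highest ratio ran from PP_1690 to PP_1691 and had 1 read at 30 °C and 1693 at 10 °C. The regions between groES and groEL (181 and 3 reads), kgdB and kgdA (64 and 1), dnaK and grpE (105 and 4) and lpdG and kgdB (94 and 4) ranked first among the lower ones, beside ORFs that were lower too. These gaps are 43 to 102 bases long, and a read that overlaps a flanking ORF is counted in both. The region next to mvaB, at 4013062 to 4013594, was also lower, with 281 and 22 reads. Intergenic regions took 21.1% (exact 95% interval 21.0 to 21.3) of the reads in ORFs and intergenic regions at 30 °C and 31.9% (31.74 to 32.04) at 10 °C.

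Of 4508 listed regions, 438 had at least 20 reads, of which 120 were higher and 118 lower when each library was scaled to its intergenic total. Scaled to the ORF total, 183 were higher and 55 lower. On that scale 346 regions had a countable ORF on their high-coordinate side. Both were higher in 94 pairs, both lower in 40 and opposite in 3. A read that overlaps both is counted in each, so part of this agreement may be the same reads. Beside the region between PP_1690 and PP_1691, the 5 highest included 1883664 to 1884609, with 1 and 1008 reads, and 1882560 to 1882707, with 0 and 215. Both adjoin PP_1690 or PP_1691 and belong to the same stretch of raised reads. The others lay at 1513068 to 1513358, with 1 and 249 reads, and at 1277368 to 1278734, with 3 and 200.

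7 regions next to 16S rRNA genes held 51.2% of the intergenic reads at 30 °C and 59.3% at 10 °C. They had 32416 and 69072 reads in the deposited tables, a ratio of 2.03 (2.00 to 2.06) scaled to ORF reads. The 7 regions did not agree. The region at 5312680 to 5313393 alone had 7342 and 32431 reads (ratio 4.21), while that at 170818 to 171387 had 9979 and 5512 (0.526) and that at 697072 to 697822 had 3422 and 3010 (0.838). In the alignments the region at 170818 to 171387 went the other way, with 1956 and 4261 reads. The regions adjoin copies of the same gene and may share sequence, which was not tested. How reads that match more than 1 place were assigned was not given, so the ratios of single regions are uncertain. Without these 7 regions, a choice made after the data were seen, the intergenic share was 11.6% at 30 °C and 15.99% at 10 °C.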

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

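No test was chosen for the values in this part, which were looked at only after the results were seen. The gene tables hold rRNA and tRNA genes outside the comparisons of the report, and both had counts above the limit that 0 reads allow. The 21 rRNA genes held 8192 reads at 30 °C and 10609 at 10 °C, a ratio of 1.23 (1.20 to 1.27) scaled to ORF reads. Reads fell in 7 of the 21 genes and covered 148 bases of them at 10 °C. Per gene this is on average shorter than 1 read, so these reads may overlap only the gene edges. Reads at an edge are also counted in the neighbouring region, so the ratio may not measure rRNA. The 74 tRNA genes held 663 reads at 30 °C and 987 at 10 °C, a ratio of 1.42 (1.28 to 1.57), with reads in 52 of them.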

How the results depend on the processing

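The alternatives that kept 1 read where no base was covered, left out the 7 regions next to 16S rRNA genes, took the amino acid biosynthesis list as first written, or set members at 0 to their bound were chosen after seeing the data. No paired analysis was possible because there was 1 library per temperature and the results come from no test. For the same reason no library could be left out.

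Of the counts of ORFs, 10 of the alternatives for higher and 10 for lower stayed within 1.5 times of 607 and 337. The count of higher ORFs was 911 without a minimum count and 147 with a minimum of 100, and that of lower ORFs was 165 with a minimum of 100 and 215 with the 3-fold rule, as these settings by construction admit more or fewer ORFs. Higher intergenic regions numbered 183 with the ORF total, 183 without a minimum and 38 with a minimum of 100, against 120. Lower ones numbered 55, 227 and 38 under the same settings and 71 with the 3-fold rule, against 118. Without the 7 regions next to 16S rRNA genes they were 138 and 88.

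The intergenic share was larger at 10 °C under each setting tried, by a ratio of 1.38 to 1.69. At 30 °C and 10 °C it was 17.5% and 29.6% when recounted from the alignments, 9.28% and 14.3% with each start and strand counted once, 12.4% and 17.4% without the 10 most abundant features of each kind, 11.6% and 15.99% without the 7 regions, and 21.7% and 32.2% with 1 read where no base was covered.

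Of 100 list medians under alternatives, 92 stayed within their interval. That interval reflects the spread of list members and is wide for small lists, so staying within it is weak evidence of stability. The catabolic median counted as within it at 0.91, and the storage median at 0.20. Across the settings the medians changed sign for the cold shock, helicase, fatty acid, flagellum, compatible solute, RNA polymerase and RNA chaperone lists. The ribosomal protein median moved to -0.60 (TMM) and -0.63 (DESeq2), that of iron acquisition to -2.28 and -2.31, and that of the respiratory chain to -2.05 (DESeq2), shifts that apply to all ORFs. Amino acid biosynthesis moved to -2.15 with a minimum of 100 (30 members), and the 3 cold shock genes had a median of 0.78 without a minimum. Flagellum and chemotaxis turned to 1.55 with a minimum of 100, where 4 abundant members remained. Setting bkdA2 and trpB to their bound left the medians of their lists at 3.63 and -1.08. The cold shock, compatible solute and storage lists with a minimum of 100 and the transposon list with any minimum gave no value.

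Of 79 named ORFs called higher or lower, 71 kept their call under TMM and 71 under DESeq2, 78 when recounted and 66 with each start and strand counted once. The latter setting compresses abundant genes by construction, since a gene has a limited number of starts. Under TMM and DESeq2 only higher calls could end, because both lowered every ratio.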

Other observations

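The gene groups, clusters and regions below were chosen after their values were seen, and so were the tests on the nusA-pnp and ribosomal protein clusters, on low-GC ORFs with at least 160 reads and on the regions next to pcnB and mvaB. The other tests were fixed after the pattern and before the result they measure.

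Several genes of sugar and glycerol use, which the lists above left out, were higher in the 10 °C library. Of 12 genes of the Entner-Doudoroff pathway and glucose breakdown 6 were countable, and all 6 were higher (median log2 ratio 2.61), 5 under TMM. Without a minimum count the median over the 11 with a read was 1.64. Of the countable genes gap-1, edd and glk are neighbours, as are zwf-1, pgl and eda. Neighbours may share a transcript, so these calls are not independent. zwf-1, glucose-6-phosphate dehydrogenase, had 14 reads at 30 °C and 192 at 10 °C (ratio 13.1, 7.60 to 24.4), and pgl had 14 and 100. Of 4 glycerol genes, which are neighbours too, glpF, glpK and glpD were higher, with 66, 75 and 27 reads at 10 °C against 7, 11 and 2, and glpR was not. Of 8 gluconeogenic and lower glycolytic genes 6 were lower, among them ppsA with 215 and 28 reads and gap-2 with 399 and 65, and tpiA was higher (2.30-fold), a call that TMM ended. The 3 genes algT, mucA and algN, an extracytoplasmic stress sigma factor and its regulators, were 15.0-fold, 10.6-fold and 9.38-fold higher.

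DNA repair genes had 9 higher and no lower members of 20 (2 lower under TMM), led by recC with 22 and 241 reads, recB with 20 and 112 and the photolyase gene phrB with 21 and 219, while recA had 63 and 69. In the division and cell wall cluster 7 of 12 genes were higher, such as ftsI with 12 and 68 reads and ftsW with 12 and 58, and 4 under TMM, whereas ftsZ had 148 and 115. The medians of these 2 groups, at percentiles 93.6 and 96.1, lay inside the central 95% of random lists. Purine synthesis had 7 lower genes of 14, with purA at 141 and 35 reads, and the glycine cleavage group 5 of 6, with gcvT-1 at 32 and 1. That group took in the serine dehydratase gene sda-2 (21 and 1 reads, lower), which is not a glycine cleavage gene. gcvT-1, sda-2, gcvP-1 and gcvH are neighbours and may share a transcript.

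The ratio of CPM was lower over the last 3 genes of the atp, sdh-suc and nuo operons than over the first 3. The differences in log2 ratio were -1.95 (95% counting interval -2.14 to -1.75), -2.71 (-2.89 to -2.52) and -0.77 (-1.20 to -0.33). In nuo the ratio did not fall steadily to the end, with 0.334 for nuoCD, 0.150 for nuoL and 0.349 for nuoN, the last gene. Whether each cluster forms 1 transcript was not tested. Correction for GC content left the difference nearest 0, that of nuo, at -0.68 (-1.12 to -0.25), and counting each start and strand once left it at -0.73 (-1.22 to -0.24), which speaks against GC content or repeated fragments as the whole cause. A general loss of distal RNA in the 10 °C library stayed open, as other clusters went both ways. In the nusA-pnp cluster the last 2 genes lay below the first 2 (-1.51, -1.66 to -1.35). In the ribosomal protein cluster rpmD, rplO and secY exceeded rpsJ, rplC and rplD by 1.47 (1.40 to 1.54), but by 0.48 (0.35 to 0.61) with each start and strand counted once. Over the whole cluster, from rpsJ to rplQ, the difference was 0.57 (0.50 to 0.65), or 0.23 (0.09 to 0.37) counted once. Within it the log2 ratio changed from secY to rplQ by -0.93 (-0.996 to -0.869), or -0.27 (-0.39 to -0.15) counted once, and from rpsJ to rplX by -0.24 (-0.32 to -0.17), or 0.02 (-0.13 to 0.18). Shorter transcripts at 10 °C, or unequal decay along them, may also be the source and were not tested.

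ORFs of low GC content had a higher median ratio than the others, though many passed no threshold. This was noticed while asking whether weakly read ORFs were higher, since the median was 0.64 among ORFs of 20 to 40 reads and -0.12 among those of at least 2000. The 186 ORFs with the lowest GC (up to 52.9%) had a median log2 ratio of 1.53 against 0.25 in the others, 107 were higher and 6 lower (92 and 11 under TMM), and 14.5% carried a symbol against 48.8%. A GC bias of sequencing strong enough to be the cause was expected to make reads of the same ORF poorer in GC at 10 °C by more than 1 percentage point. They differed in that direction, but by -0.0868 percentage points (-0.150 to -0.0236, 1120 ORFs). The limit of 1 percentage point was chosen and not derived from the size of the pattern. Each start and strand was counted once here, so the comparison says little about a bias in how often fragments were copied. The difference of medians was 1.23 (0.78 to 1.80) among ORFs with at least 160 reads, and it was 1.42 (0.88 to 1.63) after the largest uniform background was subtracted. A bias that acts on fragments longer than the 32 bases read, or a response of genes of unusual composition, could each remain and was not tested.

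The region between PP_4696 and pcnB, at 5337992 to 5338771, had 677 reads at 30 °C and 106 at 10 °C (6.70-fold lower scaled to ORF reads, 5.45 to 8.30), and the region next to mvaB was 13.4-fold lower (8.68 to 21.7). Pseudomonads encode the small RNAs CrcZ and CrcY beside these genes, which bind Hfq and so relieve catabolite repression by Hfq and Crc, but the files annotate neither. Reads did not run over from the flanking ORFs, as their density at 30 °C was at least 20.0 times (15.3 to 26.5) that of the denser flank, and with each start and strand counted once the summed ratio was 0.22 (0.18 to 0.28). Fewer of these RNAs could go with stronger repression of catabolic genes. The catabolic list had a median of 3.63, and its only member called lower was putA of proline breakdown, which the list's name does not cover. The interval of that median (-0.68 to 4.60) still took in lower values, so stronger repression stayed open. Whether the regions hold these RNAs was not tested.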
